A study of Macaca mulatta with 33 samples.

How the data were processed

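RNA from the livers of 33 macaque offspring was sequenced, 1 library per animal, when the animals were 3 years old. The samples fall into 4 groups named by maternal diet and postweaning diet, where CD is a control diet and WSD a western-style diet: 10 CD/CD, 10 WSD/CD, 6 CD/WSD and 7 WSD/WSD animals. The organism field names rhesus macaque, while the design text speaks of Japanese macaques, a closely related species. Each animal is a separate sample. Relatedness, sex and date of collection were not given in the labels used here, so p-values take the animals as independent.

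Per the labels, total RNA was extracted with the Qiagen RNeasy Mini kit, strand-specific mRNA libraries were prepared with the Swift kit, and paired-end reads were generated on a NovaSeq instrument. The submitters' processing notes name GSNAP, SAMtools and Cufflinks. Their order, their settings and the genome build are not given in the sources used here. The authors deposited 1 table of FPKM values (fragments per kilobase of transcript, scaled to the mapped fragments of each library) for 34882 Ensembl macaque genes in the 33 libraries. Its columns carry the animal numbers that stand in the sample titles, and each column was assigned to its sample by that number. All columns matched a sample. The table held no columns of fold changes or p-values, so no comparison values of the authors could be set beside those computed here.

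FPKM values are not counts. Total depth per library is therefore not given by the table, and values are not whole fragments. Genes at the lowest nonzero values gave a relative depth per library, taken as the most common ratio to CD/CD replicate 4. From a pool of 2870 low genes, 54 to 186 could be compared per library. Of these 24.1% to 50.9% lay near the most common ratio, so the relative depth is a rough estimate. It ranged from 0.53 to 1.68. The value 999999999 stood in at least 1 library for 15 genes, in all 33 libraries for 7 of them and in 31 libraries for ALB, and was treated as missing. Those 15 genes were left out of every test, so albumin is not reported.

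Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, using an intensity trend and Benjamini-Hochberg adjustment, with an adjusted p under 0.05 as the threshold. Genes with a mean FPKM of at least 0.5 and no missing value were tested, 12497 in all. All 33 libraries entered 1 model with 4 group means, so the groups share 1 estimate of the spread (29 residual degrees of freedom). Fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes. The 5 pairwise comparisons and the interaction of both diets were taken from it. Gene symbols came from the table itself for 11007 tested genes and from a table of Ensembl identifiers for 359 more, while 1131 had no name and 177 shared a symbol. Members of gene families with close copies, such as the CYP2, CYP4A and metallothionein genes, could share reads, and their values are uncertain for that reason.

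Before the data were examined, 29 gene lists were fixed, covering liver metabolism, stress and immune responses and markers of the cell types of the liver. The 27 lists with at least 4 tested members were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. The genes named in the text follow a rule fixed at the same time: in each pairwise comparison, the 10 largest increases and 10 largest decreases among genes past the threshold with their own symbol and a mean FPKM of at least 1 in the higher group. Where none passed, the 5 smallest p-values were taken. The 4 members with the largest moderated t of each list called by camera were added, and for the interaction the 5 smallest p-values. Some genes that this rule names are not reported here. Concordance of fold changes was computed across genes between comparisons that share no library, with 100 draws that permuted the diet labels within the other diet.

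Alternatives fixed before the data were examined were a pseudocount of 0.1, no filter on low values, median-of-ratios scaling, quantile normalization, only the groups compared, sample weights, a robust variance model, a term for animal numbers above 32000, only animals below 32000, the mean level of 6 Y-linked genes as a covariate, and the diet effect averaged over the other diet. XIST was not listed in the table. Chosen after seeing the data were the fits without animals numbered above 34000, with the mitochondrial share as a covariate, with number series as a factor, and within series 30, 31 or 33 alone. Number series stands for the leading digits of the animal number (30, 31, 33 and 34), which the labels do not explain. The mitochondrial share is the percent of summed FPKM in the 13 protein-coding genes of the mitochondrial genome.

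The gene test was checked on simulated data with the real means and spreads of the 12497 genes and 200 changed genes. Genes were drawn independently of each other, with the same spread in every group and no number series. The rates below therefore need not hold for the real libraries, which share structure across genes. For WSD/CD against CD/CD it recovered 25 of 62 genes changed by 0.5 on the log2 scale, 69 of 77 changed by 1 and 60 of 61 changed by 2. Of 166 calls there, 12 were unchanged genes. The shares recovered at 0.5, 1 and 2 were 27%, 72.7% and 91.5% for CD/WSD against CD/CD, 30.2%, 82.7% and 97% for WSD/WSD against CD/CD, 20.5%, 90.6% and 94.2% for WSD/WSD against CD/WSD and 28.2%, 80% and 93.2% for WSD/WSD against WSD/CD. Unchanged genes made up 9.42%, 6.37%, 3.73% and 6.43% of the calls in these 4. Permutation tests of library measures used scipy 1.17.1 in Python 3.11.15, and plots matplotlib 3.10.9.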

Results

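Liver transcriptomes were compared between 4 groups of 3-year-old macaques whose mothers ate a control diet (CD) or a western-style diet (WSD) while pregnant and nursing, and who were themselves weaned to either diet. Groups are written maternal diet/postweaning diet: CD/CD (n = 10), WSD/CD (n = 10), CD/WSD (n = 6) and WSD/WSD (n = 7). Between 15527 and 17306 genes had an FPKM above 0 in a library, and the relative depth was 1.05 ± 0.379 (SD) in CD/CD, 1.02 ± 0.190 in WSD/CD, 1.18 ± 0.185 in CD/WSD and 1.16 ± 0.350 in WSD/WSD.

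Libraries were not equally alike. The mitochondrial genome, which encodes subunits of the respiratory chain and ATP synthase, gave 2.35% ± 0.736 (SD, n = 10) of summed FPKM in CD/CD, 7.13% ± 5.60 (n = 10) in WSD/CD, 2.39% ± 1.09 (n = 6) in CD/WSD and 1.81% ± 0.414 (n = 7) in WSD/WSD. The share was higher in WSD/CD than in CD/CD (difference 4.78 percentage points, permutation p = 0.00952, adjusted p = 0.0238 over 5 comparisons, two-sided). It reached 15.78%, 11.5%, 16.08% and 7.58% in WSD/CD replicates 6, 7, 9 and 10, and 6.94% and 5.06% in replicates 2 and 3, against at most 3.46% in CD/CD. Replicates 6, 7, 9 and 10 also had the highest scores on the first principal component (39.6% of the variance). All 5 animals numbered above 34000 were in WSD/CD: these 4 and replicate 8, which had a share of 1.98%. Replicates 2 and 3 were numbered 30734 and 33337.

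**Figure D1:**
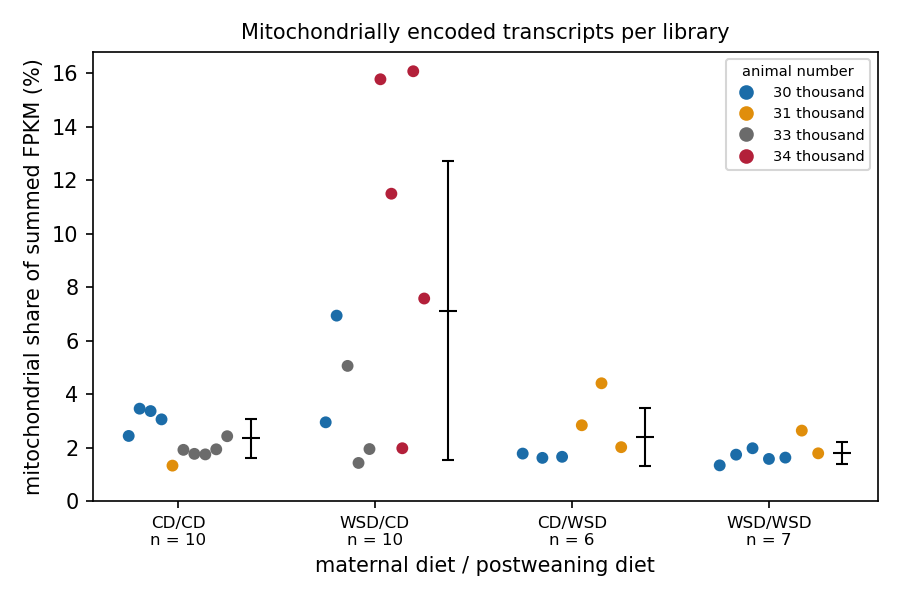
Mitochondrial share of summed FPKM (percent, y axis) in each of the 33 libraries by group (x axis), coloured by the leading digits of the animal number; bars beside the points are mean and SD. The 3 highest libraries, at 16.08%, 15.78% and 11.5%, are WSD/CD animals numbered above 34000.

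The first comparison asked what maternal WSD left in the liver of offspring weaned to the control diet. By camera, matrix and stellate cell lists stood higher and hepatocyte markers lower in WSD/CD than in CD/CD livers. The hepatocyte call was lost with an estimated correlation, and 0 genes passed with limma without the animals numbered above 34000. DLK1 (ENSMMUG00000020038), an imprinted gene of fetal liver and progenitor cells, stood at 23.5 ± 17.7 FPKM (SD, n = 10) against 8.48 ± 6.92 (n = 10), a log2 fold change of 1.37 ± 0.356 (SE, adjusted p = 0.0233), above the CD/CD mean in 10 of 10 animals. The growth factor PTN rose by 1.06 and the matrix proteoglycan OGN by 0.97 on the log2 scale. HSD17B13 (ENSMMUG00000019040), a lipid droplet protein of hepatocytes, was at 22.8 ± 18.8 FPKM against 44.6 ± 16.98 and fell by 1.33 (SE 0.386, adjusted p = 0.0328).

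Of 25 measured collagen and extracellular matrix genes 11 rose and none fell (16 rose when adjusted over the list alone), among them COL3A1 (0.77), COL6A3 (0.715) and COL5A1 (0.59). The list passed camera (adjusted p = 5.78e-17), also with an estimated correlation (adjusted p = 0.0408), with the list median above the CD/CD mean in 7 of 10 libraries. Stellate cell and fibroblast markers behaved alike, with 3 of 13 higher (PDGFRB 0.71, CYGB 0.60 and NGFR 0.64; 6 adjusted over the list alone; higher in 10 of 10 libraries; camera adjusted p = 7.95e-09, and 0.0408 with an estimated correlation). Of the 5 cholangiocyte markers, which label bile duct cells, SPP1 rose (0.54; 2 genes adjusted over the list alone; camera adjusted p = 0.000388, and 0.0408 with an estimated correlation). In the interferon response list IFI27 rose (0.62) and 17 of 19 members had a positive fold change (camera adjusted p = 1.07e-08, and 0.264 with an estimated correlation). Markers of T and NK cells, endothelial markers and cell cycle genes stood higher as lists (camera adjusted p = 0.0149, 0.0151 and 0.00492, and 0.598, 0.598 and 0.307 with an estimated correlation), but no member passed on its own.

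On the lower side, 9 of 13 hepatocyte markers fell (11 adjusted over the list alone), including SERPINA1 by 0.96, AHSG by 1.10, ASGR1 by 0.69 and the transcription factor HNF4A by 0.63. Nuclear-encoded oxidative phosphorylation genes fell in 21 of 63 cases (33 adjusted over the list alone), such as ATP5F1C (-0.64), NDUFV1 (-0.65) and COX8A (-0.69), and in the same livers the mitochondrially encoded ND2, COX3, ND5 and COX1 rose by 1.15, 1.10, 1.08 and 1.07. Fatty acid oxidation fell in 8 of 22 genes (13 adjusted over the list alone), among them BDH1 (-0.77), HADHA (-0.62) and ACADVL (-0.55). The bile acid genes NR0B2 (-1.10), SLC27A5 (-1.09), CYP27A1 (-0.81) and SLC10A1 (-1.23), the last a bile acid uptake carrier, fell among 16 measured (7 adjusted over the list alone). In the endoplasmic reticulum stress list CALR, DNAJC3 and MANF fell by 0.58, 0.54 and 0.65 (3 of 19; 11 adjusted over the list alone), and in the acute phase list SERPINA3 and FGG fell by 1.16 and 0.88 (2 of 16; 12 adjusted over the list alone). Camera called these lists lower (adjusted p = 0.000204 for hepatocyte markers, 1.79e-07 for oxidative phosphorylation, 0.000204 for fatty acid oxidation, 0.0155 for bile acids, 0.019 for endoplasmic reticulum stress and 0.00406 for acute phase). With an estimated correlation none of these 6 passed (adjusted p = 0.598 for hepatocyte markers, oxidative phosphorylation, fatty acid oxidation and acute phase, and 0.607 for the other 2). Fry, which does not set a list against all other genes, gave these 6 lists as lower. Its adjusted p was 0.00793 for oxidative phosphorylation, 0.00981 for hepatocyte markers and fatty acid oxidation and 0.0299 for the other 3. All tested genes together also stood lower, at a median log2 fold change of -0.147.

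The limma test called 190 genes higher and 1003 lower, with a median log2 fold change over all genes of -0.15. With the mean level of Y-linked genes as a covariate it called 576, 83 higher and 493 lower, 574 of them among the 1193. After median-of-ratios scaling, which moved that median to 0.01, the split was 414 higher and 313 lower, and of the genes named here SLC10A1, BDH1, HADHA, ACADVL, CALR, DNAJC3, MANF, SERPINA3, FGG, AHSG and HNF4A no longer passed (adjusted p between 0.0508 for SERPINA3 and 0.115 for MANF). Their direction was kept. Relative to the median of all genes, hepatocyte markers stood at a median of -0.565 and collagen genes at 0.65. Without the animals numbered above 34000 limma called 0 genes (999 at an unadjusted p under 0.05). DLK1 then stood at 0.80 (adjusted p = 0.652), HSD17B13 at -0.60 (0.711), COL3A1 at 0.32 (0.71) and SERPINA1 at -0.28 (0.735). A fit to CD/CD and WSD/CD alone also called 0 genes with limma (3315 at an unadjusted p under 0.05). The SE and adjusted p-values given for single genes above use the spread shared by all 4 groups. None of those genes passed in the fit to these 2 groups. Within number series 30 (2 against 4 animals) 365 genes passed, 241 higher and 124 lower, and 69 of them were among the 1193 called in all animals. Within series 33 (3 against 5) 3 genes passed, 2 higher and 1 lower, and 0 of them were among the 1193.

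Per library, the median of the 190 higher genes stood 0.79 to 1.06 above the CD/CD mean in WSD/CD replicates 6, 7, 9 and 10, and that of the 1003 lower genes between -1.33 and -0.62. Replicates 2 and 3, of series 30 and 33 with mitochondrial shares of 6.94% and 5.06%, stood at 0.78 and 0.395 for the higher and at -0.53 and -0.33 for the lower genes. Replicate 8, numbered above 34000 with a share of 1.98%, stood at 0.30 and -0.05. Without the animals numbered above 34000 the collagen, stellate cell, cholangiocyte, interferon, cell cycle, fatty acid oxidation, oxidative phosphorylation and hepatocyte lists still passed camera in the directions above (adjusted p from 1.72e-05 for collagen to 0.0284 for cell cycle). None of these 8 passed there with an estimated correlation (adjusted p from 0.144 to 0.585), and the other 5 lists missed the threshold (0.144 to 0.425). De novo lipogenesis, not called in all animals (0.842), stood higher there (camera adjusted p = 0.044, and 0.656 with an estimated correlation). Among animals below 32000 (2 against 5) the fatty acid oxidation, cell cycle, acute phase and endothelial lists missed it (0.259, 0.0536, 0.194 and 0.529), as did endoplasmic reticulum stress, whose camera direction turned (0.358, median -0.14). In that fit the list of immediate early and heat shock genes, which respond to tissue handling, stood higher (camera adjusted p = 0.000102, median 0.63, and adjusted p = 0.137 with an estimated correlation), and in all animals it did not pass (0.548). Without the animals numbered above 34000 it stood higher too (camera adjusted p = 0.0417, median 0.18, and 0.386 with an estimated correlation). Its median was 0.73 in replicate 2 and between -1.05 and -0.48 in replicates 6, 7, 9 and 10.

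**Figure D2:**
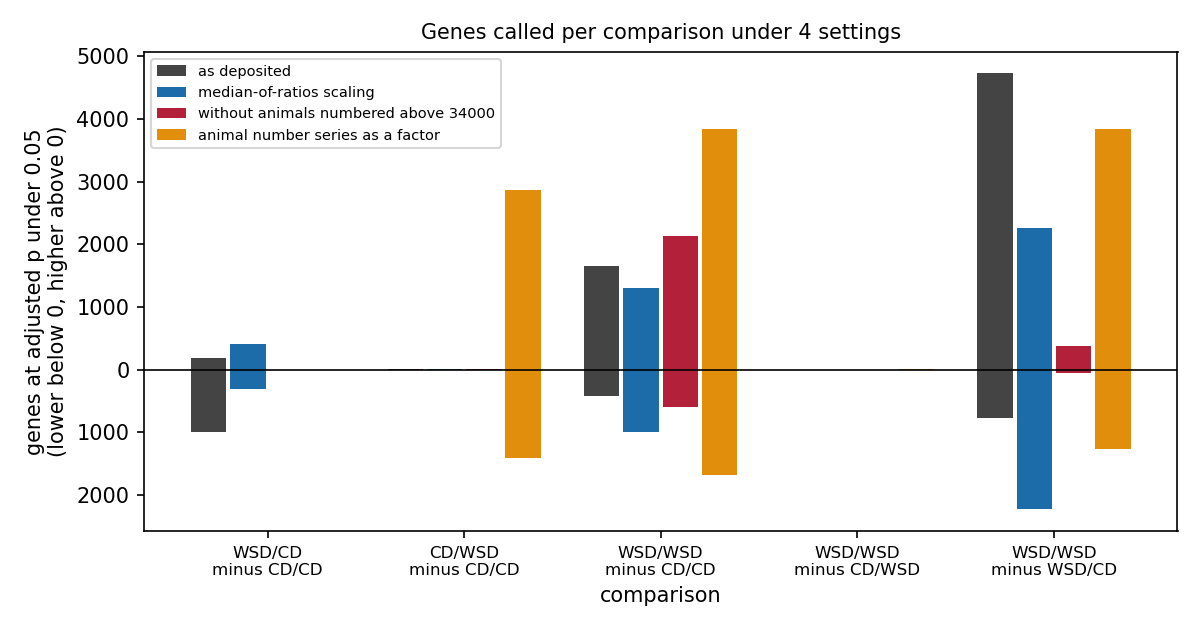
Number of genes at adjusted p under 0.05 (y axis, lower below 0 and higher above 0) in the 5 pairwise comparisons (x axis) for the deposited values and 3 other settings. In WSD/CD against CD/CD the bars of the deposited values reach 190 higher and 1003 lower, and no gene is called without the animals numbered above 34000.

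The second comparison asked what postweaning WSD did in offspring of control-fed mothers. CD/WSD livers differed from CD/CD livers in 3 genes. TMEM184A (ENSMMUG00000013080), a transmembrane protein gene, was at 7.40 ± 4.97 FPKM (SD, n = 6) against 1.84 ± 1.16 (n = 10), a log2 fold change of 1.47 ± 0.267 (SE). SVIL, which encodes the actin-binding supervillin, was at 5.79 ± 1.37 against 2.51 ± 0.642 FPKM and rose by 0.945 on that scale (SE 0.167). IL22RA1 (ENSMMUG00000063454), the interleukin 22 receptor of epithelial cells, was at 1.36 ± 0.658 against 4.73 ± 2.49 FPKM and fell by 1.24 (SE 0.225). Each had an adjusted p of 0.0176 and lay on the same side of the CD/CD mean in 6 of 6 animals.

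No member of the fixed lists passed on its own in this comparison. Cholesterol synthesis genes stood lower as a list (camera adjusted p = 9.71e-05, median log2 fold change -0.32, 6 of 6 libraries), with FDPS at -0.78, LSS at -0.68 and MVD at -0.50, while the sterol carrier gene STARD4 stood at 0.61 (1 member lower when adjusted over the list alone). De novo lipogenesis genes stood higher (camera adjusted p = 0.0191, median 0.44, 4 of 6 libraries), with THRSP at 1.06 and the lipogenic regulator SREBF1 at 0.74, but the acetyl-CoA synthetase gene ACSS2 at -1.16 (1 member lower when adjusted over the list alone). Interferon response genes stood higher (camera adjusted p = 4.43e-05, median 0.47, 4 of 6 libraries; 3 members higher when adjusted over the list alone), led by IFI6 at 1.07 and IFI44 at 0.95. Their list median stood at 0.51 to 1.07 in the 3 animals of series 30 and at -0.03 to 0.15 in the 3 of series 31. Endothelial markers (1.30 to 1.54 against -0.67 to -0.42) and Kupffer cell markers (0.98 to 1.05 against -1.58 to -0.57) split between the same animals. Oxidative phosphorylation stood lower (camera adjusted p = 0.012, median -0.10, 5 of 6 libraries; 0 members adjusted over the list alone) and cell cycle genes higher (camera adjusted p = 0.00998, median 0.24, 6 of 6 libraries; 1 member, MKI67, adjusted p = 0.175 over all genes, when adjusted over the list alone). All 5 list calls were lost with an estimated correlation (adjusted p = 0.926 for each), and among animals below 32000 the lipogenesis, interferon and cell cycle lists missed the threshold (0.343, 0.0664 and 0.36). Bile acid genes, not called in all animals (0.341), stood higher there (camera adjusted p = 0.0282, and 0.976 with an estimated correlation). The count of 3 genes depended on number series: 4883 genes passed within series 30 (3 against 4 animals), 21 within series 31 (3 against 1, the lone CD/CD animal being taken to vary like the other groups), 4271 with series as a factor, 1128 with a term for animal numbers above 32000 and 2193 among animals below 32000.

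The third comparison set animals exposed to WSD before and after weaning against CD/CD animals. As lists, lipogenic genes stood higher and oxidative phosphorylation genes lower in WSD/WSD livers by camera, but neither list passed with an estimated correlation. PRSS12 (ENSMMUG00000015260), a serine protease gene, was at 5.37 ± 3.70 FPKM (SD, n = 7) against 0.592 ± 0.209 (n = 10), a log2 fold change of 1.79 ± 0.259 (SE, adjusted p = 0.000425). CYP2C19, a drug-metabolising cytochrome P450, rose by 2.21, PPP1R3B, which targets a phosphatase to glycogen, by 1.73, the growth factor receptor gene FGFR2 by 1.70 and the basement membrane collagen gene COL4A1 by 1.58. The largest decreases were in MT1E (-1.95), a metallothionein gene, and VSIG4 (-1.37), a complement receptor of Kupffer cells. DDT (ENSMMUG00000004552), a tautomerase related to macrophage migration inhibitory factor, was at 342.7 ± 47.3 against 762.9 ± 215.2 FPKM and fell by 1.11 (SE 0.199, adjusted p = 0.00224). All of these except MT1E (6 of 7) changed in that direction in 7 of 7 animals.

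De novo lipogenesis rose in 6 of 15 genes (11 higher and 1 lower when adjusted over the list alone), among them SREBF1 (1.12), THRSP (1.47), FADS1 (0.71) and ACLY (0.44). The list stood higher in 7 of 7 libraries (camera adjusted p = 0.042, and 0.949 with an estimated correlation). Oxidative phosphorylation fell in 13 of 63 genes (17 adjusted over the list alone), including NDUFA1 (-1.19), NDUFB7 (-0.80), NDUFA6 (-0.77) and ATP5F1E (-0.77), with the list lower in 6 of 7 libraries (camera adjusted p = 3.79e-09, and 0.949 with an estimated correlation). Its median was between -0.50 and -0.24 in the 5 animals of series 30 and at -0.03 and 0.004 in the 2 of series 31. Markers of other cell types did not move as lists: of the endothelial markers CDH5 and PECAM1 rose (1.30 and 1.11) and of the Kupffer cell markers VSIG4 and CD14 fell (-1.37 and -0.65), where all but VSIG4 were named after their values were seen (camera adjusted p = 0.37 and 0.98). The other 9 Kupffer cell markers had positive fold changes (list median 0.29), and 3 were higher and 2 lower when adjusted over the list alone. The endothelial list median was above the CD/CD mean by 1.04 to 1.40 in the 5 animals of series 30 and below it in the 2 of series 31 (-0.51 and -0.46), and the Kupffer cell median was at 0.64 to 1.07 in the former and at -0.87 and -0.73 in the latter.

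In this comparison 1655 genes rose and 428 fell, with a median over all genes of 0.10. Median-of-ratios scaling gave 1309 higher and 997 lower, and ACLY and CNKSR1 then missed the threshold (adjusted p = 0.0837 and 0.0619). Among animals below 32000 the lipogenesis list missed the threshold (camera adjusted p = 0.329). Within number series 30 (5 against 4 animals) 5583 genes passed, and within series 31 (2 against 1, the lone animal being taken to vary like the others) 17, all lower.

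**Figure D3:**
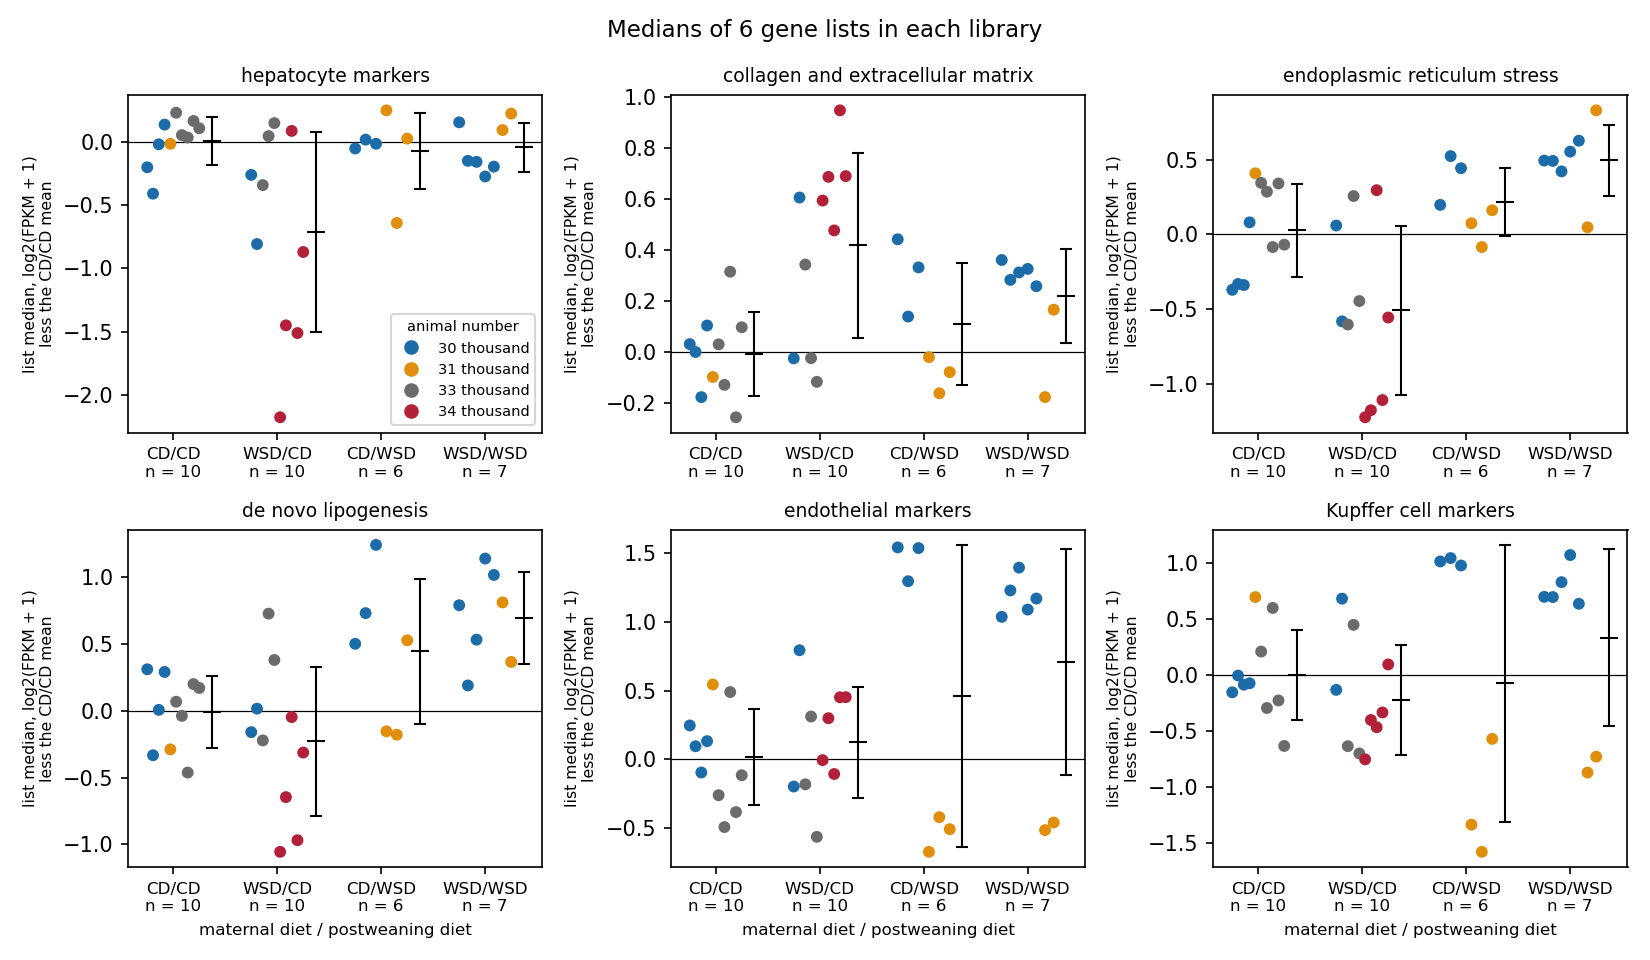
Median of 6 gene lists in each library (y axis, log2(FPKM + 1) less the mean of the CD/CD libraries) by group (x axis), coloured by the leading digits of the animal number; bars beside the points are mean and SD. Hepatocyte marker medians fall to -2.18, -1.51, -1.45 and -0.87 in 4 of the 5 WSD/CD animals numbered above 34000 (the fifth is at 0.09) and to -0.81 in WSD/CD replicate 2, numbered 30734. Endothelial and Kupffer cell markers separate WSD-fed animals of series 30 from those of series 31.

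The fourth comparison asked whether maternal WSD changed the liver of offspring that ate WSD themselves. No gene passed between WSD/WSD and CD/WSD with limma (307 at an unadjusted p under 0.05, and 5 genes with sample weights). Among the genes with the smallest p-values, CYP2C19 (ENSMMUG00000015542) was at 33.4 ± 23.02 FPKM (SD, n = 7) against 3.08 ± 2.5 (n = 6), a log2 fold change of 2.91 ± 0.623 (SE, adjusted p = 0.296) that was positive in 7 of 7 animals, and it passed with number series as a factor (adjusted p = 0.027). PRSS12 (1.06), VEPH1 (-0.44) and ENSMMUG00000058325 (1.85) each had an adjusted p of 0.962.

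As lists, cholesterol synthesis genes stood higher (camera adjusted p = 6.52e-05, 21 of 22 members above 0, 6 of 7 libraries), with INSIG1 at 0.74 and HSD17B7 at 0.53. Oxidative phosphorylation stood lower (camera adjusted p = 4.63e-13, median -0.14, 5 of 7 libraries), with NDUFA6 at -0.54, ATP5PF at -0.53, COX7C at -0.51 and ATP5F1C at -0.35. Relative to the CD/CD mean its median was between -0.50 and -0.24 in the 5 WSD/WSD animals of series 30. It was at -0.03 and 0.004 in the 2 of series 31, and ran from -0.30 to 0.14 in CD/WSD. The 2 groups held these series unequally. Genes of pericentral hepatocytes, those around the central vein, stood lower (camera adjusted p = 0.00829, median -0.07, 5 of 7 libraries), with RHBG at -0.59, OAT at -0.38 and RNF43 at -0.33, while LEAP2 was listed at 0 in all but 1 of the 6 CD/WSD libraries. No member passed on its own or when adjusted over the list alone, and with an estimated correlation each adjusted p was 0.952. Within number series 30 (5 against 3 animals) 0 genes passed (702 at an unadjusted p under 0.05), and within series 31 (2 against 3) 0 (367 at an unadjusted p under 0.05).

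The fifth comparison asked what postweaning WSD did in offspring of WSD-fed mothers. By camera, endoplasmic reticulum stress and bile acid lists stood higher in WSD/WSD than in WSD/CD livers, and matrix and stellate cell lists lower. None of these calls held with an estimated correlation. PPP1R3B (ENSMMUG00000050623) was at 37.8 ± 33.2 FPKM (SD, n = 7) against 5.91 ± 10.1 (n = 10), a log2 fold change of 2.98 ± 0.579 (SE, adjusted p = 0.000839). SCD, the desaturase that makes monounsaturated fatty acids, rose by 2.54, LIPG, the endothelial lipase, by 2.21, the sterol hydroxylase CYP8B1 by 2.12 and ELOVL2, an elongase of polyunsaturated fatty acids, by 2.08. The largest decreases included the mitochondrially encoded CYTB (-1.61), ND6 (-1.58), COX3 (-1.48) and ND1 (-1.38), and among nuclear genes ANKRD24 (-1.51), BUD13 (-1.496) and ZNF222 (-1.47). Each of these genes lay on the same side of the WSD/CD mean in 7 of 7 WSD/WSD animals. The groups still overlapped in the mitochondrial share. WSD/CD replicates 4, 5 and 8 stood at 1.43%, 1.95% and 1.98%, within the WSD/WSD range of 1.34% to 2.64%.

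In the endoplasmic reticulum stress list 15 of 19 genes rose, among them DNAJC3 (1.13), HYOU1 (1.52), MANF (1.28) and DNAJB9 (1.39), which serve protein folding in the endoplasmic reticulum. ATF4 and DDIT3, transcription factors of the same response that were named after their values were seen, fell by 0.42 and 0.61 (camera adjusted p = 0.0189, and 0.965 with an estimated correlation; counts adjusted over the list alone were the same, 15 higher and 2 lower). Bile acid synthesis and transport rose in 13 of 16 genes, also 13 when adjusted over the list alone, led by CYP8B1, ABCG8 (1.75) and SLC10A1 (1.58), with ABCG5 at 0.73 (camera adjusted p = 0.0258, and 0.965 with an estimated correlation). Hepatocyte marker medians differed too. Relative to the CD/CD mean they ran from -2.18 to 0.15 in WSD/CD and from -0.27 to 0.23 in WSD/WSD libraries. De novo lipogenesis did not pass camera (adjusted p = 0.0976), although 13 of its 15 genes rose and 1 fell, with the same counts when adjusted over the list alone.

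Collagen and extracellular matrix genes stood lower as a list (camera adjusted p = 0.000599, and 0.965 with an estimated correlation): 8 of 25 fell, including COL6A2 (-0.78) and COL6A1 (-0.73), and 4 rose, TGFBI (0.95), TIMP2 (0.83) and, named after their values were seen, COL4A1 (1.08) and LOX (0.34). Adjusted over the list alone, 9 fell and 4 rose. Stellate cell and fibroblast markers fell in 5 of 13 genes, such as TAGLN (-1.06), DPT (-0.97), CYGB (-0.75) and PDGFRB (-0.73), and RELN, named after its value was seen, rose by 1.36 (5 and 1 adjusted over the list alone; camera adjusted p = 0.00508, and 0.906 with an estimated correlation). Of the cholangiocyte markers SPP1 (-0.71) and SOX9 (-0.42) fell (2 of 5, also 2 adjusted over the list alone; camera adjusted p = 0.0448, and 0.906 with an estimated correlation). The 5 WSD/CD libraries with the highest mitochondrial shares, replicates 2, 6, 7, 9 and 10, also had the highest collagen list medians (0.59 to 0.95 above the CD/CD mean).

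Limma called 4731 genes higher and 767 lower, with a median over all genes of 0.26; after median-of-ratios scaling, which moved the median to -0.02, 2262 were higher and 2232 lower. Without the animals numbered above 34000, 384 genes were higher and 48 lower. In that fit the endoplasmic reticulum stress list still passed (camera adjusted p = 0.00971, and 0.766 with an estimated correlation) while the bile acid, collagen, stellate cell and cholangiocyte lists did not (0.0854, 0.438, 0.0829 and 0.0808). Oxidative phosphorylation and periportal hepatocyte genes, not called in all animals (0.247 and 0.594), stood lower in that fit. Their camera adjusted p was 0.00102 and 0.0183, and 0.669 each with an estimated correlation. Among animals below 32000 (7 against 2) it was the bile acid list that passed (0.000941, and 0.777 with an estimated correlation), and the endoplasmic reticulum stress, collagen, stellate cell and cholangiocyte lists did not (0.4, 0.161, 0.167 and 0.112). There the immediate early and heat shock list stood lower (camera adjusted p = 0.00749, and 0.745 with an estimated correlation). T and NK cell markers stood lower too (camera adjusted p = 0.0224, and 0.897 with an estimated correlation). Without the animals above 34000, DNAJC3 (0.88, adjusted p = 0.0169) and PPP1R3B (2.65, 0.0399) passed and SCD (1.17, 0.288) and CYP8B1 (1.45, 0.0787) did not. With the mitochondrial share as a covariate 1 gene passed, and within number series 30 (5 against 2 animals) 5186 did.

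The interaction of both diets asked whether the maternal effect differed between postweaning diets. No gene passed with limma (2453 at an unadjusted p under 0.05, and 19 with sample weights). The smallest p-values belonged to YIF1A (1.28 ± 0.279, SE), PTN (-1.47 ± 0.323), RTCB (0.83), NFATC2IP (0.73) and RNF126 (0.90), each with an adjusted p of 0.209. As lists, 11 differed by camera: cholesterol synthesis, fatty acid oxidation, bile acid, gluconeogenesis, endoplasmic reticulum stress and hepatocyte genes had positive interactions, and interferon, collagen, stellate cell, cholangiocyte and cell cycle genes negative ones. None passed with an estimated correlation (adjusted p from 0.214 for collagen to 0.754 for bile acids). Without the animals numbered above 34000 the cholesterol, bile acid, gluconeogenesis and hepatocyte lists missed the threshold (0.0779, 0.208, 0.401 and 0.477). PTN stood at 10.2 ± 4.51 FPKM in WSD/CD (n = 10), 4.19 ± 1.58 in CD/CD (n = 10) and 5.21 ± 1.74 in WSD/WSD (n = 7).

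Fold changes of postweaning WSD were set side by side in offspring of control-fed and of WSD-fed mothers, comparisons that share no animals. Across 12497 genes, which are not independent replicates, Pearson's r was 0.582 and Spearman's rho 0.595 (permutation p = 0.04 for r over 100 draws, highest of the other draws 0.609). These draws did not keep number series, in which the diets were unequally spread. In 100 draws that kept it the permutation p for r was 0.12 (other draws from -0.699 to 0.464), and within series 30 alone r was 0.746 (rho 0.76, permutation p = 0.01, the smallest that 100 draws can give). In series 30 the WSD-fed animals were numbered 30155 to 30399 and the CD-fed 30586 to 30734, and 2 animals were WSD/CD. Animal number can therefore not be told apart from diet in that value. Of the 5498 genes called in either comparison 82.7% had the same sign in both, as had 68.2% of all genes. Fold changes of maternal WSD in CD-fed and in WSD-fed offspring had an r of -0.10 and a rho of -0.12 (permutation p = 0.56 for r). Within series 30 that r turned to 0.174 (permutation p = 0.07) and among animals below 32000 to 0.117 (permutation p = 0.29). Over all animals 36.7% of the 1193 genes called in either had the same sign, against 37.9% of all genes.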

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

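The fold change with the Y-linked gene level, the count without the animals numbered above 34000, the signs in number series 33, the fit within number series 30, the animal numbers in it and the counts over other splits of the samples were chosen only after the results were seen. The slopes on the mitochondrial share and the fit with depth as a covariate were set before their values were seen, those within number series after the others.

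The first pattern is the 1193 genes that differed between WSD/CD and CD/CD. The values argue against sequencing depth, as roughly estimated here, as the whole cause, since 1220 genes passed with relative depth as a covariate. They say less on sex. With the Y-linked gene level as a covariate 576 genes passed, fewer than the 1193. Yet 97.9% of the median fold change was kept (0.551, SE 0.155, before and 0.539, SE 0.158, after), and the median adjusted p of the 1193 moved to 0.051. The kept fold change argues against sex as the whole cause only so far as that level tracks sex, which was not checked. Maternal diet acting in every number series stays open: 0 genes passed without the animals numbered above 34000 (5 against 10 animals, 999 at an unadjusted p under 0.05, limma), and 5 genes, too few to decide, were called between WSD/CD animals of series 34 and CD/CD animals of series 30 and 31, of which 60% had the same sign in series 33 (3 against 5 animals, at least as many in 32 of 56 splits). A library state that goes with a high mitochondrial share may contribute, and cannot be told apart from diet here, because slopes on the share in the other 23 libraries gave the sign of 67.6% of the genes (permutation p = 0.12, highest other draw 84.8), and within number series of 78% (permutation p = 0.14, highest other draw 86.1). With the share as a covariate 0 genes passed (1385 at an unadjusted p under 0.05), as the median fold change in the direction of the call fell from 0.551 (SE 0.155) to 0.244 (SE 0.141).

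The second pattern is the 5498 genes that differed between WSD/WSD and WSD/CD. Slopes on the mitochondrial share, estimated in the 23 libraries outside WSD/CD, gave the sign of 91.7% of them (permutation p = 0.02, highest other draw 92.3), and slopes within number series, with which the share goes in these libraries, of 88.7% (permutation p = 0.03, highest other draw 90.7). This is consistent with a library state that goes with the share as part of the difference. With the share as a covariate 1 gene passed, and the median fold change in the direction of the call went from 0.636 (SE 0.183) to 0.207 (SE 0.171). Postweaning diet stays open: the values argue against number series as the whole cause, with 5186 genes within series 30 alone (3793 shared with the 5498, same direction) and 5116 with series as a factor (3902 shared), but animal number within series 30 cannot be told apart from diet, since 0 WSD/CD animals there fell within the WSD-fed range of 30155 to 30399.

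Other splits of the same libraries into groups of the same sizes were counted, 100 per comparison with the real one included. These splits did not keep number series, so they bear on single animals grouped by chance and not on series grouped by chance. Few splits reached the real count: 3 gave at least 1193 genes in WSD/CD against CD/CD (highest other 4093) and 3 gave at least 3 in CD/WSD against CD/CD (1347). In WSD/WSD against CD/CD 2 gave at least 2083 (highest other 2914), and in WSD/WSD against WSD/CD only the real split gave 5498 (highest other 4263). These shares were not adjusted over the comparisons, so they make single animals grouped by chance less likely and do not exclude it. Splits that called several times the real count point to a structure of the samples beyond the diet groups. In splits that kept each group's number of animals in every series, 1 of 100, the real one, gave at least 1193 genes in WSD/CD against CD/CD (highest other 842). There 3 of 100 gave at least 3 in CD/WSD against CD/CD (2794), 1 of 100 gave at least 2083 in WSD/WSD against CD/CD (3) and 1 of 21 gave at least 5498 in WSD/WSD against WSD/CD (2850). Neither kind of split parts diet from series where a series holds 1 group only, as series 34 does, and with number series as a factor 1 gene passed in WSD/CD against CD/CD.

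For the counts of 0 genes with limma in WSD/WSD against CD/WSD and in the interaction (307 and 2453 at an unadjusted p under 0.05) the splits decide nothing, since all 100 give at least 0 (highest other 1). Chance was not excluded for the numbers of lists: 14 splits gave at least 13 lists in WSD/CD against CD/CD (highest other 16), 40 gave at least 5 in CD/WSD against CD/CD (16), 85 gave at least 2 in WSD/WSD against CD/CD (16), 93 gave at least 3 in WSD/WSD against CD/WSD (14), 72 gave at least 5 in WSD/WSD against WSD/CD (20) and 29 gave at least 11 in the interaction (18).

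By camera on the interaction 11 lists passed, a number that 29 of 100 splits reached, and none of them passed with an estimated correlation (adjusted p from 0.214 to 0.754), so a maternal effect that differs between postweaning diets is not established by them. Adjusted p-values were 0.00175 for cholesterol synthesis (median interaction 0.61), 0.00378 for fatty acid oxidation (0.63), 0.0333 for bile acids (0.75), 0.0198 for gluconeogenesis (0.63), 0.00791 for endoplasmic reticulum stress (0.75) and 0.0198 for hepatocyte markers (0.75). For lists with negative interactions they were 1.13e-08 for interferon response (-0.38), 3.08e-10 for collagen (-0.32), 4e-06 for stellate cells (-0.30), 0.00791 for cholangiocytes (-0.45) and 0.00378 for cell cycle (-0.15). Without the animals numbered above 34000 cholesterol synthesis (0.0779), bile acids (0.208), gluconeogenesis (0.401) and hepatocyte markers (0.477) missed the threshold and the other 7 passed, none of them with an estimated correlation (0.365 to 0.677). Among animals below 32000 bile acids passed (0.00447), as did the 5 lists with negative interactions, again none with an estimated correlation (0.268 for cholangiocytes and 0.681 for the other 5). Cholesterol synthesis (0.207), fatty acid oxidation (0.293), gluconeogenesis (0.833), endoplasmic reticulum stress (0.881) and hepatocyte markers (0.249) missed it. Some lists not called in all animals passed camera only in these fits, none with an estimated correlation. Below 32000 these were immediate early and heat shock genes (0.00152) and T and NK cell markers (0.0413). Without the animals above 34000 they were lipid droplet (0.0153) and pericentral genes (0.0104).

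In 19 of 323 pairs of a named gene and a group 1 library lay far from the rest, where chance alone marks about 1 in 20, and none of 20 pairs of a library measure and a group did. In CD/CD, FPKM stood apart for DPT at 12.2 in replicate 9 (others 21.1 to 35.2), PRF1 at 2.14 in replicate 5 (0.572 to 1.26), CLDN4 at 1.59 in replicate 1 (0.0943 to 0.709), CYP2C19 at 22.9 in replicate 10 (1.77 to 7.09), and SPARCL1 at 45.5 and COL4A1 at 6.4 in replicate 8 (8.69 to 18.9 and 1.5 to 3.18). In WSD/CD they were ACADVL at 36.5 and LIPG at 9.19 in replicate 8 (13.7 to 22.9 and 0.533 to 2.79) and SPP1 at 6.37 in replicate 2 (1.47 to 3.33). In CD/WSD they were LEAP2 at 4.79 in replicate 3 (the others listed at 0) and RNF43 at 8.29 in replicate 4 (3.15 to 4.57). In WSD/WSD they were HSPA13 at 4.2, CNKSR1 at 2.4 and PCSK6 at 76.4 in replicate 6 (8.04 to 10.7, 0.0518 to 0.223 and 101 to 124), DNHD1 at 6.28 and RNF43 at 1.09 in replicate 3 (0.107 to 1.2 and 3.1 to 4.91), ELOVL2 at 44.2 in replicate 5 (23.4 to 29.6), and ANKRD24 at 14.2 and SLC10A1 at 206 in replicate 7 (7.57 to 8.67 and 144 to 164).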

How the results depend on the processing

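The fits without animals numbered above 34000, with the mitochondrial share or number series, and within series 30, 31 or 33 were chosen only after the data were seen. Of the called lists' tests across settings 310 kept direction and side of the threshold, 172 lost the call and 9 turned direction; of named genes 2031 kept both, 107 gained and 607 lost the call, and 30 turned direction. Calls moved least with a pseudocount of 0.1 and a robust variance model. Relative depth ran from 0.53 to 1.68, and without counts its effect on low genes was not measured. No paired analysis was possible because each animal gave 1 library, belonged to 1 diet group and had no relatedness given. The labels give no replicate numbers, so those used here follow the animal number within each group. Unless stated, the cause was not tested. Comparisons are named by their first group where CD/CD is the second.

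Genes called were, without a filter on low values (more genes tested), 623 in WSD/CD, 9 in CD/WSD and 2 in WSD/WSD against CD/WSD. Median-of-ratios scaling gave 727 in WSD/CD and 21 in CD/WSD, and quantile normalization 632 and 10, with 5 lists in WSD/WSD against CD/WSD and 8 in WSD/WSD against WSD/CD. With only the groups compared (fewer libraries) there were 0 in WSD/CD, 5 in CD/WSD and 3409 in WSD/WSD. Sample weights gave 1817 in WSD/CD, 5294 in CD/WSD, 4914 in WSD/WSD, 5 in WSD/WSD against CD/WSD and 19 in the interaction, and the robust variance model 1 in WSD/WSD against CD/WSD. The effect averaged over the other diet gave 0 genes for maternal diet (1207 at an unadjusted p under 0.05, limma) and 4762 for postweaning diet. The averaged maternal count was also 0 with median-of-ratios scaling, quantile normalization and without the animals above 34000. It was 349 (38 higher, 311 lower) with sample weights, 135 (106 and 29) among animals below 32000 and 223 (136 and 87) within series 30. With the Y-linked gene level 576 passed in WSD/CD and 1 in WSD/WSD against CD/WSD, and the concordance of the postweaning effect was 0.581 (p = 0.05).

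With an estimated correlation camera called 3 lists in WSD/CD and 0 in each of CD/WSD, WSD/WSD, WSD/WSD against CD/WSD, WSD/WSD against WSD/CD and the interaction. Fry, which asks another question, called 0 in CD/WSD, WSD/WSD and WSD/WSD against CD/WSD, 9 in WSD/WSD against WSD/CD and 1 in the interaction. Those 9 included endoplasmic reticulum stress (fry adjusted p = 0.00127), lipogenesis and bile acids (0.00289 each), all higher. In WSD/CD fry called lists too, among them collagen and stellate cells higher and oxidative phosphorylation lower (0.00793 each). The interferon, cell cycle, endothelial and T and NK cell lists there missed the threshold (0.0681 to 0.571).

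With the animal number term CD/WSD had 1128 genes and 3 lists, WSD/WSD 3909 genes and 1 list, WSD/WSD against CD/WSD 1 gene and WSD/WSD against WSD/CD 2 lists. Among animals below 32000 there were 173 genes in WSD/CD, 2193 genes and 3 lists in CD/WSD, 4851 genes and 1 list in WSD/WSD, 1 gene in WSD/WSD against CD/WSD, 3571 genes and 3 lists in WSD/WSD against WSD/CD and 63 genes in the interaction. There the concordance of the maternal effect turned to 0.117 (p = 0.29), DNAJB9 and STAB1 in WSD/CD to 0.204 and -0.059, EPCAM and SREK1IP1 in WSD/WSD against WSD/CD to -0.04 and 0.05, and the endoplasmic reticulum stress list in WSD/CD and in the interaction turned direction (adjusted p = 0.358 and 0.881).

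Without animals numbered above 34000 WSD/CD had 0 genes (999 at an unadjusted p under 0.05, limma), CD/WSD 8, and WSD/WSD against WSD/CD 432 genes and 3 lists, with STAB1 and VWF in WSD/CD at -0.122 and -0.017. With the mitochondrial share there were 0 genes (1385 at an unadjusted p under 0.05) and 4 lists in WSD/CD, 161 genes in CD/WSD, 8 lists in WSD/WSD, 7 in WSD/WSD against CD/WSD, 1 gene and 9 lists in WSD/WSD against WSD/CD and 3 lists in the interaction. In that fit FGA, COX3, ND2, GZMB, STAB1 and STAB2 in WSD/CD turned to 0.042, -0.013, -0.035, -0.129, -0.106 and -0.08, and ND1 and SREK1IP1 in WSD/WSD against WSD/CD to 0.024 and 0.026. The endoplasmic reticulum stress list in WSD/CD (adjusted p = 0.97) and the bile acid (0.66), gluconeogenesis (0.951) and hepatocyte (0.66) lists in the interaction turned too. COX3, ND2 and ND1 belong to the genes that make up the share, so values near 0 were built into that fit for them. Their turns are among those of named genes counted above and say nothing on the processing.

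With number series as a factor WSD/CD had 1 gene, CD/WSD 4271 genes and 1 list, WSD/WSD 5523 genes and 1 list, WSD/WSD against CD/WSD 2 genes and 5 lists and WSD/WSD against WSD/CD 2 lists, with STAB1 and VWF in WSD/CD at -0.088 and -0.023. Within series 30 WSD/CD had 365 genes, CD/WSD 4883 genes and 2 lists, WSD/WSD 5583 genes and 1 list, WSD/WSD against CD/WSD 5 lists, WSD/WSD against WSD/CD 3 lists and the interaction 70 genes, and the concordance of the maternal effect turned to 0.174 (p = 0.07). There DNAJB9 and STAB1 in WSD/CD turned to 0.373 and -0.027, RRM2 in CD/WSD to -0.024, EPCAM in WSD/WSD against WSD/CD to -0.289, and the endoplasmic reticulum stress list turned in WSD/CD and in the interaction (adjusted p = 0.193 and 0.486). Within series 31, with 1 CD/CD animal taken to vary like the other groups, CD/WSD had 21 genes and 11 lists, WSD/WSD 17 genes and 8 lists and WSD/WSD against CD/WSD 6 lists. ACLY, MCM2, MCM5 and SREBF1 in CD/WSD were then at -0.043, -0.081, -0.112 and -0.402, and ATP5F1C in WSD/WSD against CD/WSD at 0.055. Within series 33 WSD/CD had 3 genes, the acute phase list turned (adjusted p = 0.992), and GZMB, MCM5, STAB1, THBS2 and VWF were at -0.103, -0.023, -0.035, -0.017 and -0.129.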

Other observations

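The comparison of number series 31 with 30 was made after the data had been examined, and its counts with covariates and over splits were set before their values were seen.

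Among the 13 WSD-fed animals, markers of Kupffer cells, the resident macrophages of the liver, and of endothelial cells were far lower in number series 31 (n = 5) than in series 30 (n = 8), in a limma fit with maternal diet as a term. Of 11 Kupffer cell markers 9 fell (median log2 fold change -2.09), such as the scavenger receptor CD163, at 13.2 ± 3.84 FPKM (SD) against 79.8 ± 9.58 (-2.52, adjusted p = 7.07e-07), CD5L (-2.61) and MARCO (-2.12). Of 10 endothelial markers 9 fell (median -1.77), among them PECAM1 (-2.14), CDH5 (-2.18), KDR (-1.79) and LYVE1 (-1.75). Camera gave an adjusted p of 1.5e-08 for Kupffer cells and 1.66e-10 for endothelium, and with an estimated correlation adjusted p = 0.238 and 0.0348. Per library, the Kupffer list median stood 0.64 to 1.07 above the CD/CD mean in all 8 WSD-fed animals of series 30 and between -1.58 and -0.57 in all 5 WSD-fed animals of series 31, while the CD/CD libraries ran from -0.63 to 0.70. The CD-fed animals did not show this split. In series 30 the 4 CD/CD animals stood at -0.152 to -0.002 and WSD/CD replicates 1 and 2 at -0.13 and 0.685. The lone CD/CD animal of series 31 stood at 0.699, and at 0.545 for endothelial markers. VSIG4, another Kupffer cell marker, stood at -0.475 (adjusted p = 0.104).

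Other lists moved in the same comparison, none of them past the threshold with an estimated correlation. Oxidative phosphorylation rose in 13 of 63 genes and none fell (camera adjusted p = 2.79e-13, and 0.227 with an estimated correlation). Collagen and matrix genes fell in 13 of 25 cases (0.00343, and 0.403 with an estimated correlation), inflammatory genes in 7 of 10 (0.00343, and 0.27) and monocyte and macrophage markers in 3 of 6 (0.0173, and 0.192). T and NK cell markers fell in 5 of 12 genes (0.0374, and 0.628) and interferon genes in 9 of 19 (0.05 after rounding, just under the threshold, and 0.686). Stellate cell markers fell in 6 of 13 genes, with no call for the list (0.0562, and 0.473). Lists of hepatocyte (0.0213, and 0.529), periportal (0.0185, and 0.473), pericentral (0.0443, and 0.403) and cholangiocyte genes (0.0392, and 0.27) stood higher, with 1, 0, 1 and 0 members higher and 0, 1, 0 and 0 lower.

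In that comparison 319 genes rose and 2882 fell. So far as the Y-linked gene level tracks sex, the values argue against sex as the whole cause, with 2474 genes past the threshold with that covariate. They also argue against sequencing depth, as roughly estimated here, with 3234. Of 100 splits within maternal diet 1, the real one, gave as many genes, and the highest other gave 2. The splits do not exclude chance, because this comparison was picked after the data had been examined. A library state that goes with the mitochondrial share, at 2.74% ± 1.03 (SD, n = 5) in series 31 and 1.67% ± 0.182 (n = 8) in series 30, may account for part: with the share as a covariate 725 genes passed, and the median fold change went from 0.60 (SE 0.132) to 0.415 (SE 0.168), both smaller and less certain. What the number series stands for is not given in the labels, and no biological explanation was tested.

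Against all CD/CD animals, the 8 WSD-fed animals of series 30 differed in 5493 genes (4189 higher and 1304 lower) and the 5 of series 31 in 0 with limma (1392 at an unadjusted p under 0.05). With fewer animals, that 0 does not show that series 31 was like CD/CD. Among its lists, Kupffer cell (median -1.146), endothelial (-0.499) and cholesterol synthesis genes (-0.354) stood lower and lipogenesis higher (0.261). Camera adjusted p was 8.87e-13, 3.08e-05, 4.23e-05 and 0.00497, and 0.189 to 0.535 with an estimated correlation. Within CD/CD, where diet was the same, 5 animals of series 33 differed from the 5 of series 30 and 31 in 1653 genes, 1245 higher and 408 lower.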
